A study of Mus musculus with 6 samples.

How the data were processed

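Gene expression was measured in lacrimal glands of C57BL/6 mice at 2 stages, embryonic day 16.5 (E16.5) and adulthood (3 months), with 3 arrays per stage. Per the labels, the replicates of each stage were biologically independent, RNA of the E16.5 glands was isolated with one kit (Nanoprep) and RNA of the adult glands with another (Microprep), the RNA was amplified and labelled with biotin, and a single dye was read. The arrays were long-oligonucleotide MEEBO arrays, whose probes were designed from exons of mouse genes. Because the kit goes with the stage, stage and kit cannot be told apart in any comparison.

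The deposited values are linear spot intensities in scaled units, with 34266 features on each array. How the scanner output was corrected for background and scaled is not given in the sources used here. The following was read from the values. On each array, all but 0 to 10 values lay within 0.01 of a whole multiple of that array's lowest value, and the highest multiples, 65482 to 65489, lay just under the top of a 16-bit scanner range (65535). The values therefore have the form of whole scanner units with a floor of 1 unit, multiplied by 1 constant per array. That constant was 0.326 to 0.350 on the E16.5 arrays and 2.68 to 3.33 on the adult arrays, a ratio of means of 8.98. A feature at the floor, or at the top of the scanner range, on every array consequently carries a deposited value about 8.98 times higher on the adult arrays. Values of at least 65000 scanner units are called saturated below.

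The features are numbered from 396 to 35473, and the sources used here do not pair these numbers with genes. Of the numbers, 5891 happen to equal an Entrez gene ID, but 34222 of the steps between neighbouring numbers are exactly 1, so they were read as running spot numbers and no gene was named from them. The 35 gene lists and the naming of genes fixed before the data were examined could therefore not be used, nor could probes of a gene be combined. Every feature was tested as its own row, control spots could not be recognised or left out, and a gene with several probes counts several times. The result names planned for genes thus refer to features. Following the rule for named genes, the features with the largest fitted difference past the threshold, and with no overlap between the stages, were taken, limited to 2 per direction since numbers without a gene name say little. No feature, array or column was left out of the main comparison.

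Intensities were transformed as log2(intensity + 16). The medians of the arrays differed by more than 0.1 on this scale, so the arrays were quantile normalized, as planned for that case. Differences are adult minus E16.5 on this scale, which understates the change of dim features. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, all 6 arrays, stage as the only term), with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. A feature at the floor or saturated on every array of a stage has only a bound there. For a named feature, the fold was computed as "at least": the bright stage's mean normalized log2 value against the dim stage's mean of, per array, the higher of the feature's own value and the lowest value above the floor. Single values per array were compared by exact two-sided permutation of the 6 arrays, which cannot give a p below 0.1 with 3 arrays against 3. The number of arrays limits the precision of every value.

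The procedure was tested on simulated arrays for this comparison, with the levels of the E16.5 arrays, the replicate spread of both stages, and 200 of 34266 features changed, drawn from those above the floor on all 6 arrays. It recovered 1 of 50 features changed 1.5-fold, 10 of 50 features changed 2-fold, 36 of 50 changed 4-fold and 37 of 50 changed 8-fold, with 7 false calls among 34066 unchanged features. With features at the floor on all 6 arrays left out of the simulated fit, 1, 15, 40 and 47 of 50 were recovered among 29771 features, with 6 false calls. The criterion first set for this test, more than 40 of 50 features recovered at 8-fold, was not met with all features (37) and was met in the second simulation (47), which was added after that failure. The criterion was then replaced by fewer than 50 false calls and median estimated differences close to the true ones, which both simulations met. Features at the floor on all arrays, which have almost no spread, were kept in the main comparison as planned, so it may miss part of the real changes. How large a part the simulation cannot tell. With only 200 features changed, the adjustment was stricter than in the real comparison. With these floor features left out of the real comparison, 7563 features were higher in adult and 8021 in E16.5 glands, against 7038 and 8061 with them.

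Alternatives set before the data were examined were no quantile normalization, centring on the array median, other offsets, a filter on dim features, an intensity trend with a robust prior, array weights, a test against a minimum change of 1.5-fold, the replicate number as a block, and leaving out each array. A common floor, a common ceiling, dimming of the E16.5 arrays, and fits without floor or saturated features were added after seeing the data, as were the limits of 200, 33 and 50 scaled units and of 65000 scanner units used below.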

Results

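To describe how the lacrimal gland, the exocrine gland that secretes the watery part of tears, changes between its branching stage in the embryo and maturity, transcript levels were profiled in glands of C57BL/6 mice at E16.5 and at 3 months of age. Each stage was represented by 3 arrays, and each array carried 34266 features. A feature is 1 oligonucleotide spot, given here by its number because no gene names were used. The 2 stages differed far more than their replicates did. Across features, log2 values correlated at 0.992 to 0.993 between E16.5 replicates and at 0.986 to 0.988 between adult replicates, but at only 0.811 to 0.834 between arrays of different stages. The first principal component, on which the stages lay apart, held 92.7% of the variance, and the second held 2.56%.

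The arrays of the 2 stages differed in brightness before scaling. The mean feature read 1417 ± 45.6 scanner units on E16.5 arrays and 331 ± 21.2 on adult arrays (SD, n = 3 each). The median feature read 53 ± 2.65 scanner units on E16.5 arrays and 7.67 ± 2.08 on adult arrays. The floor held 21.4% ± 0.719 of the features on E16.5 arrays and 37.1% ± 3.03 on adult arrays, and 4495 features were at the floor on all 6 arrays. Saturation affected 90.3 ± 5.51 features per E16.5 array and 17.7 ± 0.577 per adult array. In scaled units the measurable range ran from 0.334 to 21899 on the average E16.5 array and from 3.00 to 196683 on the average adult array. For each of these measures the arrays of one stage all lay on one side of those of the other, which gives p = 0.1 by exact permutation, the smallest value this design allows.

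**Figure D1:**
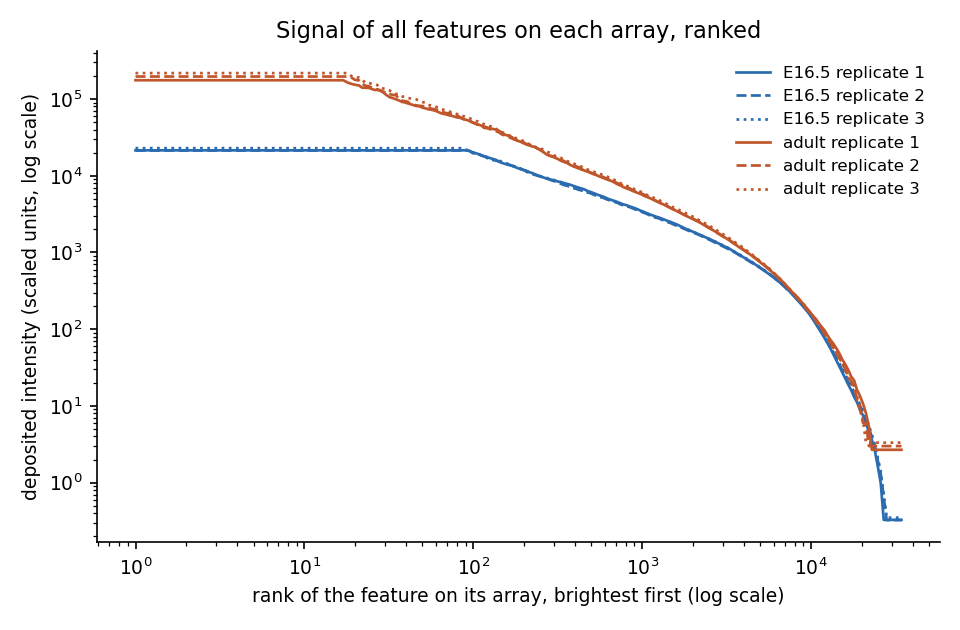
Deposited intensity in scaled units (log scale) of every feature against its rank on the array, brightest first (log scale), with 1 line per array. The flat parts at the left are saturated features and those at the right are features at the floor; both lie about 8.98 times higher on the adult arrays.

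A large part of the measured transcriptome differed between the stages. Of the 34266 features, 7038 (20.5%) were higher in adult glands and 8061 (23.5%) were higher in E16.5 glands at an adjusted p below 0.05 (limma), and 19167 were not called. Differences of at least 2-fold were found for 4711 features higher in adult and 4946 higher in E16.5 glands, of at least 4-fold for 1997 and 2389, and of at least 16-fold for 433 and 592. The remaining 5442 calls, 36.0% of the total, were smaller than 2-fold. All 15099 called features had 3 arrays of one stage above the 3 of the other. Such separation was seen for 53.1% of all features, where chance alone gives 10%.

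The balance between the directions depended on the scaling and on the filter. After quantile normalization 46.6% of the called features were higher in adult glands. A feature counts here as measured in both stages if it was neither at the floor nor saturated on all arrays of either stage. Of these 23771 features, 6880 were called higher in adult and 5983 higher in E16.5 glands (53.5% adult) in the same fit. This filter is uneven: 9393 features lay at the floor on all adult arrays and 5508 on all E16.5 arrays. It takes out 2044 E16.5-higher calls with the adult arrays at the floor, but only 135 adult-higher calls with the E16.5 arrays at the floor. The adult share among the features kept is therefore raised by the selection. With the deposited values as they stand, 16116 features were higher in adult and 6777 in E16.5 glands (70.4% adult), but the calls for adult then included each of the 4495 features that lay at the floor on all 6 arrays. With a common floor for all arrays and no quantile normalization, the counts were 8204 and 6059 (57.5% adult). Centring the arrays on their median gave a near-even balance of 7862 and 7702 (50.5% adult), and so did quantile normalization with dim features left out, at 7260 and 7089 (50.6% adult). At differences of at least 2-fold, 48.8% of the called features were higher in adult glands after quantile normalization (4711 against 4946), 51.4% with median centring (5149 against 4870), 59.2% with the deposited values (6034 against 4156) and 59.2% with a common floor and no quantile normalization (5836 against 4030). The median shift of all features in the deposited values was 0.22 (log2, adult minus E16.5). The 4495 features at the floor on all 6 arrays share this same difference by construction. The median shift was 0 with a common floor as well as after quantile normalization, where these floor features also lie at 0. In each setting the median thus fell among tied floor features, so it cannot tell whether the other features shifted. For the features measured in both stages, the median after quantile normalization was 0.1045. This value does not measure a shift either, because the normalization makes the arrays alike in distribution and the filter is uneven.

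**Figure D2:**
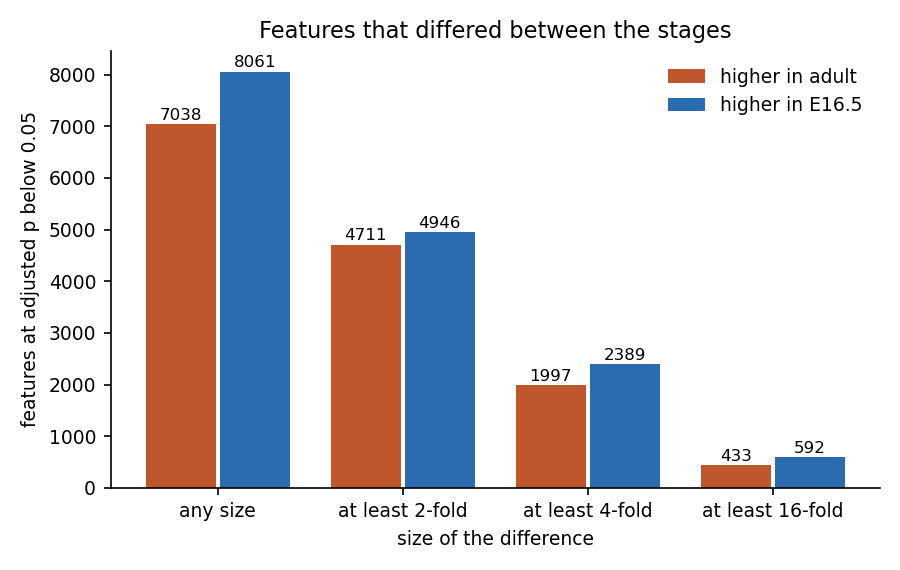
Number of features at an adjusted p below 0.05 (limma, y axis) by minimum size of the difference (x axis), with 1 bar for features higher in adult and 1 for features higher in E16.5 glands. After quantile normalization more features were higher in E16.5 than in adult glands in each class, from 8061 against 7038 at any size to 592 against 433 at 16-fold or more. With the deposited values this order turned at any size and at 2-fold or more.

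The share of features that were called was much lower among the dim ones. Of the 15676 features with a mean level under 5 on the log2(intensity + 16) scale, 17.0% were called. These calls were uneven, with 706 higher in adult and 1957 higher in E16.5 glands. Features at the floor on all 6 arrays fall in this class, and the offset shrinks the differences of the others. The lower share therefore does not show that dim transcripts differed less often. In the classes from 5 to 7, 7 to 9, 9 to 11 and above 11, the share was 63.7%, 69.6%, 69.0% and 67.8%. Calls higher in adult glands were the more numerous from 5 to 7 (2501 against 2284), 7 to 9 (1902 against 1807) and 9 to 11 (1366 against 1320). Above 11 they were the fewer (563 against 693). The surplus of E16.5-higher calls in the main comparison thus lay in the lowest and the highest class. Both classes are open to effects of the processing. At the low end the floor was worth 3.00 scaled units on the average adult array and 0.334 on the average E16.5 array. At the high end quantile normalization removes the wider upper range of the adult arrays (99th percentile 15738 against 7931). These surpluses therefore cannot be read as traits of dim or bright transcripts. The median SD between replicates was 0.03 in E16.5 and 0 in adult glands in the class under 5, which holds the 4495 features at the floor on all 6 arrays, 0.17 and 0.28 from 5 to 7, and 0.16 and 0.14 above 11.

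**Figure D3:**
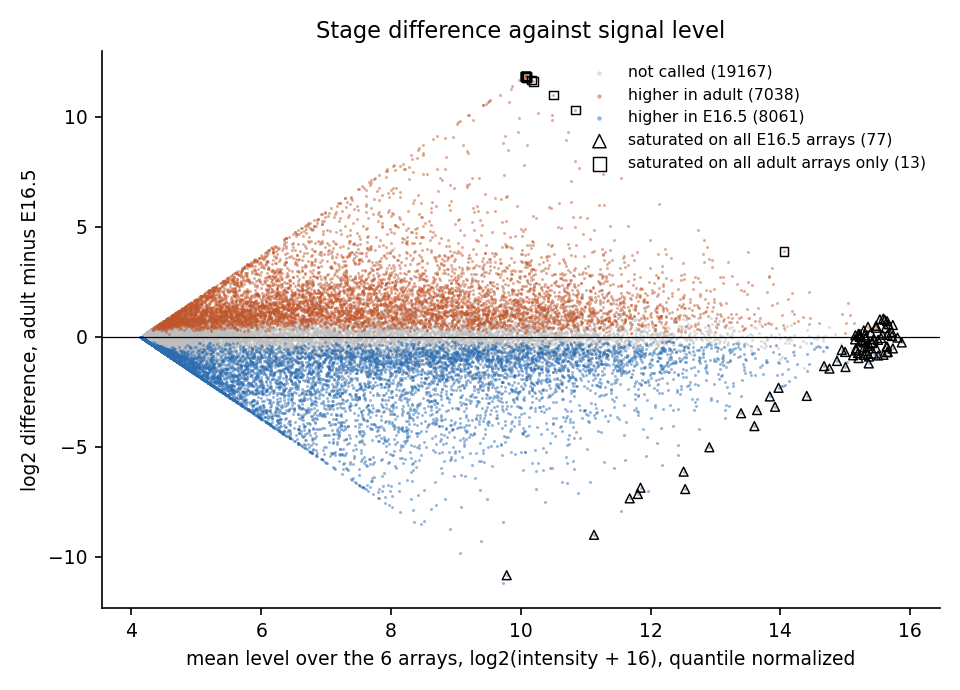
Log2 difference, adult minus E16.5, of every feature (y axis) against its mean level over the 6 arrays as log2(intensity + 16) after quantile normalization (x axis). Colours give the call and open symbols mark the 77 features saturated on all E16.5 arrays and the 13 saturated on all adult arrays but not on all E16.5 arrays.

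The features with the largest fitted differences spanned nearly the full range of the scanner, so that only bounds of their differences were measured. Feature 12570 was saturated on all 3 adult arrays (196660 ± 21020 scaled units, SD, n = 3) and at the floor on all 3 E16.5 arrays (0.334 ± 0.0136), and was at least 3681-fold higher in adult glands (adjusted p = 5.56e-10 by limma). Feature 2761 was likewise saturated on all adult arrays and at the floor on 2 of the 3 E16.5 arrays, with the same bound of 3681-fold (adjusted p = 1.17e-09 by limma). In the other direction, feature 2216 read 21402 ± 76.3 on E16.5 arrays, 2 of which were saturated, and lay at the floor on all adult arrays (3.00 ± 0.321). It was at least 1823-fold higher in E16.5 glands (adjusted p = 1e-05 by limma). Feature 20640 was saturated on all E16.5 arrays and at the floor on 2 adult arrays, and was at least 1518-fold higher in E16.5 glands (adjusted p = 2.62e-05 by limma). Where the arrays of a stage were saturated or at the floor, the spread between them does not measure biological variation, which limits what these p-values show. The bounds depend on offset and scaling, and the folds given are lower bounds only with the main offset and quantile normalization. The fitted log2 difference of feature 12570 was 11.86, 10.11 with a common floor and ceiling and 14.58 with an offset of 1.326. That of feature 2216 was -11.18, -10.14 with the deposited values, -9.632 with an offset of 50 and -13.9 with an offset of 1.326. The directions of the 4 features did not change in any alternative run for them. Which features differed most cannot be ranked among those that are only bounded.

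**Figure D4:**
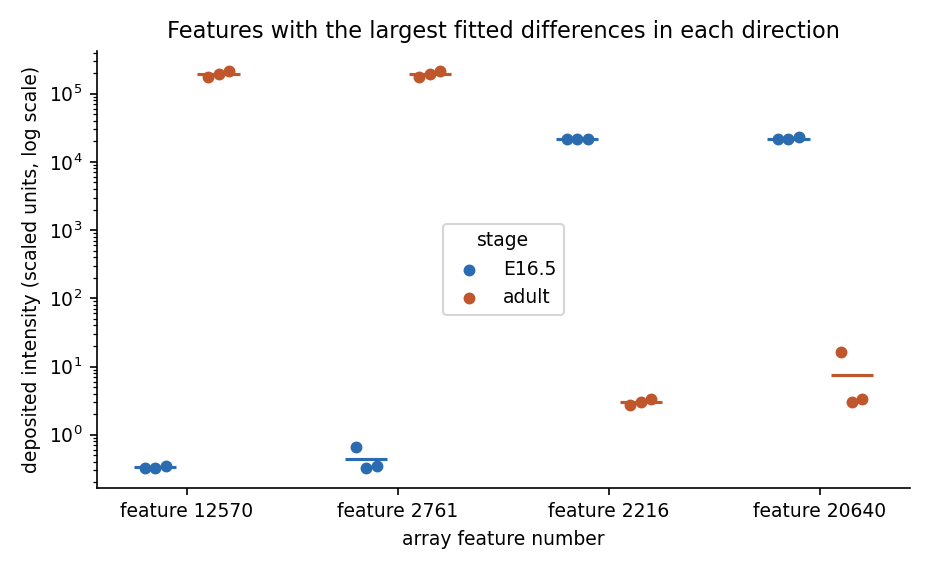
Deposited intensity in scaled units (log scale) on each array for the 2 features with the largest fitted difference in each direction; points are arrays and lines are means of 3 arrays. Features 12570 and 2761 lie at or near the floor on E16.5 arrays and at the ceiling on adult arrays, and features 2216 and 20640 show the reverse.

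Features detected at one stage only were found in both directions. At the floor of each array, 2800 features were above the floor on all E16.5 arrays and at the floor on all adult arrays, against 145 with the opposite pattern. These counts compare arrays of unequal brightness. With the E16.5 scanner units divided by 8.98 and rounded down, so that 36.8% to 38.1% of features were at the floor on these arrays, the counts were 1225 and 946. Divided by the ratio of the mean scanner units (4.28) or of the medians (6.91) instead, they were 1754 and 458 or 1404 and 721. With limits in scaled units that both stages could measure, 402 features read at least 200 on all adult arrays and below 33 on all E16.5 arrays, and 377 showed the opposite pattern. A value below 33 does not mean that a feature was undetected. The median feature read 17.7 scaled units on E16.5 arrays and 22.6 on adult arrays. These 2 counts thus describe large differences and not detection at one stage only. For 2044 of the 8061 features called higher in E16.5 glands (25.4%), the other stage was at the floor on all arrays. The same held for 135 of the 7038 called higher in adult glands (1.92%). At most a lower bound of the fold was measured for these features. The floor was worth 0.334 scaled units on the average E16.5 array and 3.00 on the average adult array. Where E16.5 values lay under the adult floor, the direction was therefore not measured either. With a common floor, 7164 features were called higher in E16.5 glands after quantile normalization and 6059 without it.

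At the upper end of the range, saturation limited what could be compared. Of the 17 features saturated on all adult arrays, 12 had an E16.5 mean below 50, 4 were saturated on all 6 arrays and 1 was intermediate. Of the 77 features saturated on all E16.5 arrays, 15 had an adult mean no higher than the highest E16.5 ceiling in scaled units. All 15 were called higher in E16.5 glands, a direction that this selection largely fixes in advance. For the other 62 the adult mean lay above that ceiling and the direction was not resolved. After quantile normalization 19 of these 62 were called higher in E16.5 glands, 11 higher in adult glands and 32 were not called.

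The upper part of the signal range was wider on the adult arrays, a difference that quantile normalization removes before the main comparison. The 75th percentile of the scaled intensities was similar, 226 ± 2.68 on E16.5 and 237 ± 3.01 on adult arrays, whereas the 95th percentile was 2134 ± 26.5 and 3299 ± 132, and the 99th was 7931 ± 267 and 15738 ± 543 (SD, n = 3 each). The ratio of the 99th to the 75th percentile, which no scaling constant changes, was 35.1 ± 1.13 on E16.5 arrays. It was 66.3 ± 2.16 on adult arrays, 1.89 times higher. The arrays of the stages did not overlap in this ratio (p = 0.1, exact permutation test, the smallest possible). The 100 brightest features held 13.4% ± 0.376 of the summed intensity on E16.5 arrays and 30.9% ± 1.23 on adult arrays (p = 0.1, exact permutation test). Most of these features were saturated on E16.5 arrays and 17 to 18 were on adult arrays, so both shares are lower bounds and their order is not settled.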

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

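The settings with a common floor or ceiling, dimmed E16.5 arrays, a limit of 10 scanner units, or floor or saturated features left out were chosen after the results were seen. The number of arrays limits every test, and features at the floor or saturated carry only bounds. Across 21 alternatives, counts of features changed at least 2-fold stayed within 1.5 times their values in both directions (3576 to 6034 higher in adult, 3799 to 6155 higher in E16.5), but their balance turned from 4711 against 4946 to 6034 against 4156 in the deposited values, 5836 against 4030 with a common floor, 5748 against 4028 with a common floor and ceiling (all 3 without quantile normalization) and 5149 against 4870 with median centring. At any size the balance turned in these settings and without dim features (7260 against 7089). The counts at any size also stayed within 1.5 times, except that the deposited values without quantile normalization gave 16116 higher in adult (against 6777), 4495 of them at the floor on all arrays, and a test against 1.5-fold gave 4102 and 4461, as its stricter null requires. Of the features called both in the deposited values and after quantile normalization, 158 of 13748 had opposite directions. Leaving out single arrays gave 5719 to 6648 higher in adult and 6907 to 7358 higher in E16.5 glands. With the replicate number as a block the counts were 5749 and 6372. For same-numbered arrays, the deviations from the stage means correlated at 0.08, 0.05 and -0.0003 across features. Of the 6 arrays, 4 deviated most like their own number. With so few arrays, these values neither show nor exclude that same-numbered arrays shared more than a number. The lowest correlation between replicates, 0.986, moved to 0.968 with an offset of 1.326, 0.990 with an offset of 50 and 0.982 without dim features; the cause was not tested. Features above the floor at E16.5 only and in adults only numbered 1225 and 946 with E16.5 arrays dimmed to a like detection limit, 1754 and 458 to a like mean, 1404 and 721 to a like median, and 5355 and 239 above 10 scanner units. The adult over E16.5 ratio for the 100 brightest features fell from 2.30 to 0.679 with a common ceiling, which by construction sets nearly all 100 to one value. The named features kept direction and call in all 20 alternatives run for them. Gene lists and combining of probes were not run for want of gene names.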

Other observations

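All tests in this part except the count over other splits of the arrays were chosen after the results were seen. Within a stage, few features varied strongly between arrays. A range of more than 2 on the log2 scale was seen for 96 features among the adult arrays and for 50 among the E16.5 arrays, and no feature showed it in both. Adult replicate 1 lay more than 2 above both other adult arrays in 24 features, adult replicate 2 in 5 and adult replicate 3 in 21. Adult replicate 3 lay as far below both others in 5 features, adult replicate 1 in 1 and adult replicate 2 in 0. Among E16.5 arrays the counts above both others were 2, 9 and 4.

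Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, gave as many called features: 15099 by limma. The highest of the others was 0, with at most 595 features at an unadjusted p under 0.05. Each of the other splits mixes the stages in both groups, so the stage difference counts there as spread within the groups. That they called no features was thus largely set in advance, and the count cannot tell whether chance could give the real one. With 10 splits no share under 0.05 can be reached either.

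The 19.3-fold excess of features detected at E16.5 only over those detected in adults only may be a matter of array brightness. Dividing the E16.5 scanner units by 8.98, which gives the arrays a like detection limit in scaled units, lowered the ratio to 1.29, but it then also brings the shares of features at the floor close together, which by itself makes the counts alike. Matching the medians gave 1.95 and matching the means 3.83. The outcome thus depends on how brightness is matched, and how much of the excess comes from brightness was not decided.

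The surplus of adult-higher calls in the deposited values may stem largely from the unequal floor. A first test asked whether features at the floor on all 6 arrays made up more than 50% of the surplus of 9339, and it was undecided at 48.1% (4495 features). It was replaced by the share that a common floor removes, 77.0%, leaving 2145, when that outcome could already be read from the alternatives, so this value is weak evidence. The unequal floor is not the whole source: with a common floor 57.5% of the calls were still for adult, and 55.2% to 59.4% when single arrays were left out of that fit. Whether the rest is a property of the glands or of the scaling stays open.

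The larger share of adult signal in the 100 brightest features could come from the scanner ceiling of the E16.5 arrays, but this was not decided. With a common ceiling the adult share was 8.92%, yet 94.7 ± 0.577 features per E16.5 array and 258 ± 6.43 per adult array (SD, n = 3 each) then lay within 1% of that ceiling or above it, so the share follows from the array totals. The wider upper range is not accounted for by the ceiling, because the 99th percentile of the E16.5 arrays reached at most 37.6% of their ceilings. Too much background subtracted on the adult arrays would need a constant of 72.4 scanner units, close to the adult 75th percentile of 79.7, and even then the 99th over the 95th percentile would be 4.54 ± 0.0567 (SD, n = 3), above the highest E16.5 array at 3.78. The stage itself and the RNA kit, which cannot be told apart, stay open and were not tested. The same holds for other differences between the arrays that go with the stage, such as their brightness.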
